A study of Mus musculus with 12 samples.

How the data were processed

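Cells labelled as haematopoietic stem cells (HSC) from the mouse aorta-gonad-mesonephros region (AGM), fetal liver and bone marrow were profiled one cell per well in 96-well plates. The labels give neither the age of the animals nor the surface markers of the sort. Per the labels' protocols, nuclei were captured on magnetic beads and taken away, and the cytoplasmic polyadenylated RNA was made into libraries by a modified single-cell tagged reverse transcription method (scSTRT-seq). The measured RNA is therefore meant to be cytoplasmic, but the nuclear RNA Malat1 was found in 99.8% to 100% of cells of each tissue, so nuclear RNA was not absent.

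The authors deposited 1 table per plate that holds counts of unique molecular identifiers (UMIs) per gene symbol and well, without normalization. Per the submitters' processing notes, UMI-tools, featureCounts and SAMtools were used with the mm10 genome. Versions, the annotation and the strand setting are not given in the sources used here, so overlapping, antisense and near-identical genes may share reads. Over all 12 plates 22307 gene symbols occurred, of which 98.1% matched the mouse gene names at hand. No row lacked a gene, and no column of another sample was set aside. Positions of genes come from the GENCODE annotation of GRCm38, the same build.

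Each plate carries an origin code in its title. Both AGM plates share 1 code, fetal liver plates 1 to 3 and plates 4 and 5 carry 1 code each, and so do bone marrow plates 1 to 3 and plates 4 and 5. For bone marrow plates 4 and 5 the tissue comes from the titles, since their other labels give the cell type as the source and no tissue, and whether they hold the same sorted population as plates 1 to 3 is not known. Nothing in the labels says whether a code is an animal or a pool, and plates with one code were not treated as separate animals. UMI counts were therefore summed over the kept cells of all plates with one code, which gave 1 AGM, 2 fetal liver and 2 bone marrow libraries.

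A well was kept as a cell with at least 1000 genes, at least 3000 UMIs and under 20% of UMIs from mitochondrial genes. Of 1152 wells 1020 were kept and 132 were left out. No doublet caller was run, because cells were sorted singly into wells. Cells were neither clustered nor typed.

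The summed counts were compared in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test, with TMM normalization, the filterByExpr filter on low counts and 1 model over the 5 libraries. The model had 2 residual degrees of freedom, a prior of 18.0 degrees of freedom and a common biological coefficient of variation of 0.619. Because AGM has 1 library, its spread was not measured, and it was assumed to vary like the other libraries. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 among 15472 tested genes. Every adjusted p given for a gene comes from this test. An error after a log2 fold change is that change divided by the square root of the test's F statistic. It only approximates a standard error, and it can be too small where a tissue has few UMIs. CPM are counts relative to TMM-scaled library sizes, averaged over the libraries of a tissue. A fold against a tissue with no UMI is a lower bound against a floor of 3 UMIs over all of its libraries, and with 1 to 3 UMIs the ratio of summed UMIs is given with its exact 95% counting interval. Both use TMM-scaled library sizes. A bound with 1 plate left out is the lowest over the plates of both tissues, and it falls also where only depth is lost.

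Gene lists for cell states, pathways and other cell types were fixed before the data were examined, 30 in number, of which 29 were tested. Each was tested with camera at its preset correlation between genes, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. With the estimated correlation 0 of 87 tests passed, and the smallest adjusted p was 0.173. That setting rests on the 2 residual degrees of freedom of the model and so had little power. For MHC class I presentation, fetal liver against AGM, the estimated correlation was -0.0312, yet camera gave an adjusted p of 0.185. Failing there does not by itself show that a list owes its call to correlation between genes. Some lists did have high estimated correlations. In bone marrow against AGM these were 0.980 for cytosolic ribosomal proteins, 0.351 for G2 and M phase and 0.206 for S phase. Calls of such lists at the preset correlation may owe to it. Counts of members that rose or fell use the adjustment over all tested genes. "Adjusted over the list alone" means the same p-values adjusted among the members.

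Genes are named by a rule fixed at the same time. For each comparison it takes the 8 largest rises and 8 largest falls among called genes with a mean of at least 50 CPM in the higher tissue and plates that do not overlap, without predicted genes, Xist and Y chromosome genes. It adds up to 4 members of each list with the smallest adjusted p, or the 2 most abundant where none passed, and 8 genes by which blood stem cells are told from their progeny.

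For measures per cell, each kept cell was thinned to 20000 UMIs, and shallower cells were left out. This makes UMIs equal between cells, not molecules. Thinning kept 98.6% of AGM, 92.3% of fetal liver and 92.7% of bone marrow cells. Plate values of fetal liver and bone marrow were compared by an exact two-sided permutation test over plates. With 5 against 5 plates its smallest p is 0.00794. That p measures the spread between plates, some of which share an origin code. Shares of cells carry exact (Clopper-Pearson) 95% intervals, and beside a share of 0 the limit given is 3 counts of the total.

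UMI values per detected gene were uneven. The median per plate ran from 2 to 18, while 24.7% to 38.1% of the values were 1. A molecule may thus have given several UMIs, to an extent that differed between plates, so intervals and floors cover counting error only. For this reason the fits were repeated on the number of cells with at least 1 UMI and with at least 2 UMIs of a gene, alternatives chosen after seeing the data. These counts were scaled by TMM to the genes detected, which differ between tissues, and they saturate for abundant genes.

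The fit was tested on simulated counts with the mean of each gene over the real libraries, their library sizes and the dispersion trend over abundance. In these counts 200 genes, drawn from the more abundant ones only, were changed 2-fold, 4-fold or 8-fold. For fetal liver against AGM it recovered 4.48%, 58.2% and 84.8% of them. For bone marrow against fetal liver it recovered 19.4%, 74.6% and 87.9%, and for bone marrow against AGM 8.96%, 61.2% and 83.3%. False calls numbered 6 of 104, 1 of 122 and 4 of 106 calls, among 15472 genes. The rates do not cover genes of low abundance. Genes had no dispersion of their own beside the trend, so false calls from genes with a wider spread were not checked. Each gene had the same dispersion in every simulated library, so the run does not check the spread assumed for AGM. Changes of 2-fold were therefore mostly not detectable.

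Alternatives to the scaling, the test, the filters, the cells and the libraries are given in the closing section. Without fetal liver plate 4 the library of its origin code holds plate 5 alone, which nearly lacked 59 genes found on the other fetal liver plates. All libraries share an estimate of the spread, so that setting bears on every comparison. They used DESeq2 1.42.0 and limma 3.58.1. The limma fit took each plate as a library with the origin code as a random block, so the test and the unit changed together. Its consensus correlation of plates with one code was -0.0982, so it made no allowance for plates of one code being alike. Measures per cell and figures used Python packages, among them scipy 1.17.1 and pandas 2.3.3.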

Results

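Transcriptomes of single cells labelled as haematopoietic stem cells were compared between the AGM, the embryonic region where the first such cells arise from endothelium, the fetal liver, where they expand, and the bone marrow. The cells came from a mouse line built for lineage tracing, and the series was designed to read expression beside lineage, chromatin and DNA methylation. Here the RNA tables of 12 plates were used, of which 2 were from AGM, 5 from fetal liver and 5 from bone marrow. After filtering, 143 AGM, 454 fetal liver and 423 bone marrow cells remained with 83152493 UMIs in all. Plate totals ran from 2596681 to 15977740 UMIs. The summed libraries held 24323995 UMIs for AGM, 16516736 and 11525376 for fetal liver, and 24699454 and 6086932 for bone marrow.

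A cell had a median of 159228 UMIs in AGM, 54303 in fetal liver and 59558 in bone marrow. After thinning to 20000 UMIs the plate medians of detected genes averaged 3368 ± 10.96 (SD, n = 2 plates) in AGM, 3098 ± 309.7 (SD, n = 5) in fetal liver and 1914 ± 157 (SD, n = 5) in bone marrow. Without thinning the medians over cells were 5513, 4117 and 2631 genes. Thinning made UMIs equal but not molecules, since the median UMIs per detected gene ran from 2 on fetal liver plate 5 to 18 on bone marrow plate 1. Log2 CPM of plates correlated across genes, which are not independent replicates, at a median of 0.852 within an origin code, 0.836 between codes of one tissue and 0.786 between tissues.

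**Figure D1:**
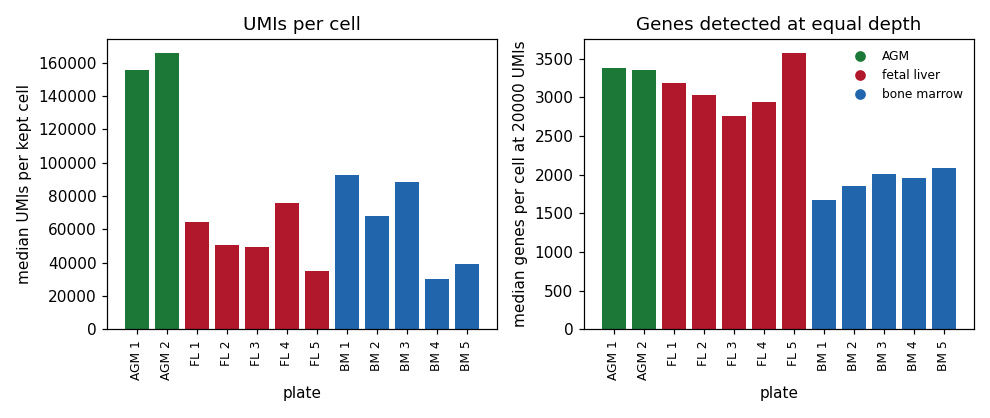
Bars show, for each plate, the median UMIs per kept cell (left) and the median genes detected per cell after thinning to 20000 UMIs (right), coloured by tissue. AGM plates were the deepest, with medians of 155534 and 165904 UMIs, and bone marrow plates had the fewest genes after thinning.

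Xist and Y chromosome transcripts were read as a check of the origin codes. Fetal liver plates 1 to 3 held 820 Xist and 1 Y chromosome UMIs and bone marrow plates 1 to 3 held 1100 and 4. Fetal liver plates 4 and 5 held 1 and 1032 and bone marrow plates 4 and 5 held 0 and 705. The AGM library held 512 Xist and 511 Y chromosome UMIs. Both tissues with 2 codes thus had 1 code with Xist and 1 with Y chromosome transcripts.

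Between AGM and fetal liver, 18 of 33 endothelial genes fell and 11 of 17 genes of MHC class I presentation rose, with no list call at an estimated correlation. Nrp1, a co-receptor for vascular endothelial growth factor, stood at 147 CPM in AGM and at 1 UMI in fetal liver (4038-fold, counting interval 724 to 159511). Gja4, a connexin of arterial endothelium, fell from 115 to 0.168 CPM (log2 fold change -9.28 ± 0.78, adjusted p = 1.99e-07), and Mmrn2, an endothelial matrix protein, from 93.5 to 0.247 CPM (-8.37 ± 0.88). Fetal liver plates 1 to 3 and plates 4 and 5 had 0.247 and 0.0885 CPM of Gja4 and 0.493 and 0 CPM of Mmrn2. Psmb9, a subunit of the immunoproteasome, rose from 17.9 to 190.1 CPM (3.41 ± 0.31). Of 15472 tested genes 452 were higher and 296 lower in fetal liver.

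Further leading falls were Tspan18, Acta2 (smooth muscle actin) and Edn1 (endothelin 1), which had 96.4, 56.2 and 54.1 CPM in AGM and 3, 2 and 2 UMIs in fetal liver. Their ratios were 884 (interval 302 to 4292), 774 (214 to 6397) and 744 (206 to 6149.8). Crip2, a LIM domain protein, fell from 144 to 0.487 CPM (0 and 0.973 in the fetal liver origins of plates 1 to 3 and plates 4 and 5). Hbb-y, the embryonic beta-globin, was at least 573-fold lower, with 62.4 CPM in AGM and no UMI in fetal liver, but AGM plates 1 and 2 had 91.2 and 8.71 CPM, 1 AGM cell held 42.9% of its AGM UMIs and the lowest bound with 1 plate left out was 80.1-fold. Its call was lost without AGM plate 1 (adjusted p = 0.0828).

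Of 33 tested endothelial markers 18 fell and the others did not pass (21 fell adjusted over the list alone, camera adjusted p = 1.67e-21, adjusted p = 0.185 with an estimated correlation). Plvap, of the endothelial fenestral diaphragm (chromosome 8, 71497765 to 71511752), fell from 199 to 7.57 CPM (log2 fold change -4.72 ± 0.42), and Cldn5, a tight junction protein, from 256 to 6.25 CPM. Cdh5, the endothelial cadherin, fell 50.1-fold. At least 1 UMI of Cdh5 was found in 97.2% of AGM cells (interval 93.0 to 99.2%) and 4.63% of fetal liver cells, and after thinning in 68.1% and 2.63%. The median AGM cell held 15 of 26 markers found in the endothelial list alone, against 4 in fetal liver, and after thinning 9 against 3.

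**Figure D2:**
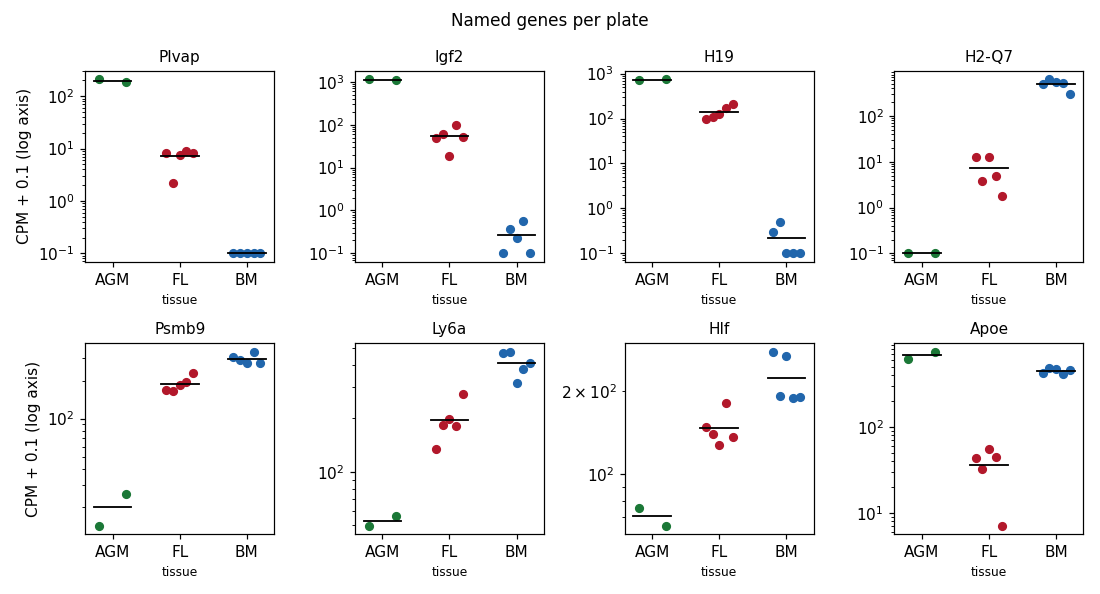
Each point is the CPM of 1 plate plus 0.1, on a log axis, for 8 named genes, and black lines are the means over plates of AGM (2 plates), fetal liver (FL, 5) and bone marrow (BM, 5). Plvap, Igf2 and H19 are highest in AGM, H2-Q7, Psmb9, Ly6a and Hlf in bone marrow, and Apoe is lowest in fetal liver.

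Of 17 genes described as fetal in blood stem cells 6 fell between AGM and fetal liver and the others did not pass (8 fell adjusted over the list alone, camera adjusted p = 7.08e-08, adjusted p = 0.185 with an estimated correlation). The growth factor Igf2 (chromosome 7, 142650766 to 142666816) fell from 1114 to 65.4 CPM (log2 fold change -4.09 ± 0.31, adjusted p = 4.41e-08). Igf2bp1, an RNA-binding protein, fell 6.28-fold. H19, the imprinted neighbour of Igf2, fell 4.97-fold. Among 27 imprinted genes 5 fell, Igf2, H19 and Cdkn1c among them (8 fell adjusted over the list alone, camera adjusted p = 3.93e-06, adjusted p = 0.380 with an estimated correlation). Cdkn1c, a brake on the cell cycle, fell 7.13-fold.

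Of 17 genes of MHC class I presentation 11 rose in fetal liver and the others did not pass (14 rose adjusted over the list alone, camera adjusted p = 5.70e-13, adjusted p = 0.185 with an estimated correlation). Psmb8, another immunoproteasome subunit, rose from 60.7 to 356 CPM, and H2-T23, a non-classical class I chain, rose 12.5-fold. Of 38 interferon response genes 7 rose and 1 fell (13 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000918, adjusted p = 0.380 with an estimated correlation), with Ifi47, an interferon-induced GTPase, at 9.52 and 112 CPM. The leading rises held Mndal and Ifi203, interferon-inducible members of the p200 family (log2 fold changes 6.81 ± 0.40 and 4.30 ± 0.35), Mzb1, an endoplasmic reticulum chaperone known from B cells (6.01 ± 1.17), and Bank1, a B cell scaffold protein (5.30 ± 0.83). They also held Tnfrsf18 (5.66 ± 0.50), Tbxas1, the thromboxane synthase (5.66 ± 0.37), the protease gene Napsa (5.32 ± 0.41) and Socs2, a suppressor of cytokine signalling (4.73 ± 0.43). The call of Mzb1 was lost (adjusted p = 0.151) without fetal liver plate 4.

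Of 28 immediate early genes, which respond within minutes to stimulation or tissue dissociation, 6 fell between AGM and fetal liver (1 rose and 16 fell adjusted over the list alone, camera adjusted p = 1.30e-09, adjusted p = 0.185 with an estimated correlation). Jun fell from 201 to 23.95 CPM. Fos had 30.4 CPM in AGM and 1 UMI in fetal liver (836-fold, interval 149.7 to 33073), with 31.0% of its AGM UMIs in 1 cell. Of 54 genes of G2 and M phase 5 fell (7 fell adjusted over the list alone, camera adjusted p = 1.29e-05, adjusted p = 0.555 with an estimated correlation), with Cenpf, a kinetochore protein, at 308 and 121 CPM. Runx1, a transcription factor needed for the emergence of blood from endothelium, fell 3.76-fold, and the granule enzyme Mpo fell from 266 to 26.0 CPM. The apolipoprotein Apoe fell 16.7-fold. Without fetal liver plates 1 to 3 the log2 fold change of Jun was -3.85 instead of -3.06. The calls of Jun, Fos, Cenpf and Runx1 were lost (adjusted p = 0.271, 0.0631, 0.115 and 0.0993) without plate 4.

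Among genes used to tell stem cells, Ly6a (Sca-1, chromosome 15, 74994877 to 74998031) rose 3.66-fold in fetal liver (adjusted p = 0.000170) and Hlf, a stem cell transcription factor, rose 2.18-fold (adjusted p = 0.0237). Slamf1 (CD150) rose from 0.428 to 16.2 CPM and Flt3 rose 3.75-fold, a call made in 17 of 30 alternatives. Kit, Procr, Cd34 and Cd48 did not pass, with log2 fold changes of -0.39 ± 0.29, -0.45 ± 0.31, -0.36 ± 0.25 and 1.73 ± 1.07. Without fetal liver plate 4 the calls of Hlf, Slamf1 and Flt3, fetal liver against AGM, were lost (adjusted p = 0.489, 0.176 and 0.328). Hlf also lost its call without fetal liver plates 4 and 5 and without bone marrow plate 5 (adjusted p = 0.211 and 0.0689). Of 12 genes of the mitochondrial genome, read as a sign of RNA quality, 1 rose (5 rose adjusted over the list alone, camera adjusted p = 0.0830, adjusted p = 0.792 with an estimated correlation, adjusted p = 0.00487 with each plate a library), with a median log2 fold change of 1.84. It was mt-Co1, at 106 CPM in AGM and 729.6 and 247 CPM in the fetal liver origins, a call made in 25 of 29 alternatives. AGM rested on 1 library, so tissue and origin cannot be told apart there. The limma fit counted below took plates as libraries, with the origin code as a random block. The count of 748 calls dropped to 181 without fetal liver plate 4, 426 without bone marrow plate 5, 479 without fetal liver plates 4 and 5 and 348 with cells with at least 1 UMI counted, and rose to 2218 with both tissues fitted alone, 2186 or 2164 without 1 bone marrow origin, 1809 with cells with at least 2 UMIs counted and 2170 with limma (1002 and 1168 higher and lower). Without cells holding at least 5 markers of another cell type, which left out 138 of 143 AGM cells, 428 and 129 genes were higher and lower, and 177 of the 748 calls were among them.

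Between fetal liver and bone marrow, 11 of 17 fetal stem cell genes and 16 of 54 genes of G2 and M phase fell and 9 of 17 MHC class I genes rose, with no list call at an estimated correlation. H19 fell from 147 to 0.0993 CPM (log2 fold change -9.77 ± 0.45, adjusted p = 1.40e-11), Igf2 from 65.4 to 0.153 CPM (-8.87 ± 0.47) and the RNA-binding protein gene Igf2bp3 from 56.7 to 0.951 CPM (-6.78 ± 0.75). H2-Aa, H2-Eb1 and H2-Ab1, chains of MHC class II, rose 179.7-fold, 167-fold and 97.1-fold. Bone marrow plates 1 to 3 and plates 4 and 5 had 0.199 and 0 CPM of H19 and 0.0397 and 1.86 CPM of Igf2bp3. The log2 fold change of H2-Ab1 without fetal liver plates 4 and 5 was 7.22 instead of 6.6. In bone marrow 414 genes were higher and 318 lower.

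Igf2bp1 had 51.9 CPM in fetal liver and 2 UMIs in bone marrow (826-fold, interval 228 to 6829). A UMI of H19 was found in 80.6% of fetal liver and 1.18% of bone marrow cells. Id3, an inhibitor of basic helix-loop-helix factors, fell from 118 to 0.0993 CPM, the adaptor gene Grap from 92.3 to 0.496, Mzb1 from 87.9 to 2.07 and the calponin gene Cnn3 from 93.8 to 3.07. Bone marrow plates 1 to 3 and plates 4 and 5 had 0.199 and 0 CPM of Id3, 0.993 and 0 of Grap, 0.0397 and 4.10 of Mzb1 and 5.20 and 0.931 of Cnn3. The call of Mzb1 was lost (adjusted p = 0.0588) without fetal liver plate 4. Of 17 fetal stem cell genes 11 fell and the others did not pass (13 fell adjusted over the list alone, camera adjusted p = 1.37e-09, adjusted p = 0.310 with an estimated correlation). Hmga2, a chromatin protein of fetal stem cells, fell 5.84-fold. Of the imprinted genes 6 fell (3 rose and 7 fell adjusted over the list alone, camera adjusted p = 0.0318, adjusted p = 0.493 with an estimated correlation).

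The rises in bone marrow were led by Sdsl, a serine dehydratase-like gene, which rose from 0.524 to 178 CPM (log2 fold change 8.23 ± 0.60). The class I genes H2-Q7 (chromosome 17, 35439155 to 35443773) and H2-Q6 (chromosome 17, 35424850 to 35430055) rose from 7.01 to 471 CPM and from 0.899 to 128 CPM. These neighbours are near-identical in sequence, so the split of reads between them is uncertain. Klf9, a Krüppel-like factor, and the channel gene Cngb1 rose 64.2-fold and 51.8-fold. Fetal liver plates 1 to 3 and plates 4 and 5 had 1.05 and 0 CPM of Sdsl, 10.05 and 3.98 of H2-Q7, 1.36 and 0.443 of H2-Q6 and 1.85 and 0.619 of Cngb1. Of the MHC class I genes 9 rose and the others did not pass (12 rose adjusted over the list alone, camera adjusted p = 7.82e-11, adjusted p = 0.310 with an estimated correlation), with H2-K1 and H2-D1, the classical class I chains, at 602 and 447 CPM in fetal liver and 1758 and 1293 CPM in bone marrow. Of the interferon response genes 10 rose (19 rose adjusted over the list alone, camera adjusted p = 5.52e-09, adjusted p = 0.310 with an estimated correlation), among them Ifi27 (3.20-fold) and Trim30a (2.29-fold, a call made in 23 of 30 alternatives). The calls of Ifi27 and Trim30a were lost (adjusted p = 0.128 and 0.180) without fetal liver plate 4. Trim30a also lost it without either fetal liver origin (adjusted p = 0.0816 and 0.0974).

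**Figure D3:**
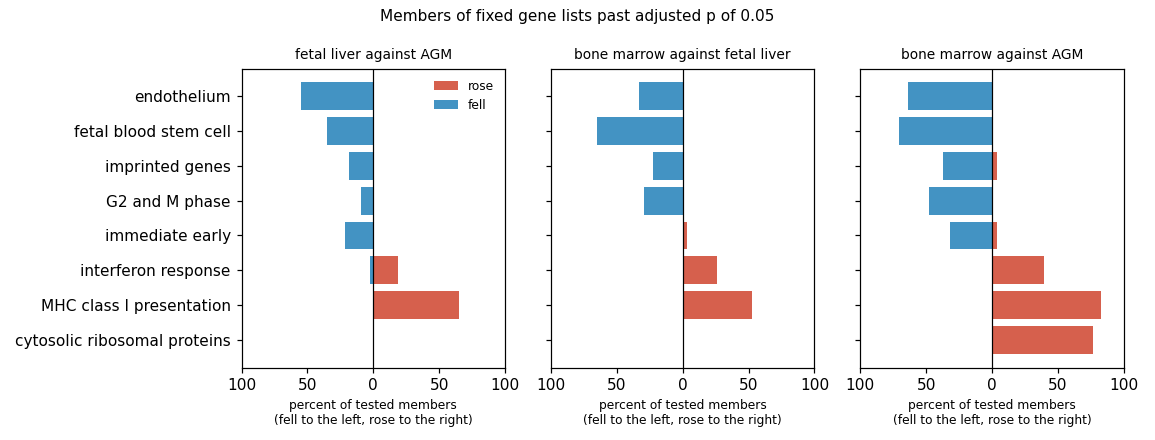
Bars give the percentage of tested members of 8 fixed gene lists that fell (left of 0) or rose (right of 0) at an adjusted p under 0.05, for each of the 3 comparisons. Part of the endothelial and of the fetal stem cell genes fell in each comparison and part of the MHC class I genes rose in each. No list call held at an estimated correlation, a setting with little power here. Of 77 ribosomal protein genes, which moved almost as one (estimated correlation 0.980), 59 rose between AGM and bone marrow.

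Of 54 genes of G2 and M phase 16 fell in bone marrow and the others did not pass (23 fell adjusted over the list alone, camera adjusted p = 1.33e-07, adjusted p = 0.569 with an estimated correlation), and of 48 S phase genes 4 fell (1 rose and 12 fell adjusted over the list alone, camera adjusted p = 0.000698, adjusted p = 0.623 with an estimated correlation). Ccnb1, the mitotic cyclin, fell 5.96-fold, Cenpa, the centromeric histone, 3.15-fold, Cdk1 2.41-fold, Tyms, the thymidylate synthase, 1.87-fold and Gmnn, the licensing inhibitor geminin, 1.91-fold. Both de novo DNA methyltransferases fell, Dnmt3b 3.97-fold (adjusted p = 3.07e-05) and Dnmt3a 2.43-fold (adjusted p = 0.00426), while the list of 18 genes of the methylation machinery did not pass (camera adjusted p = 0.879, adjusted p = 0.926 with an estimated correlation). The log2 fold change of Ccnb1, -2.58 in all, was -1.89 without bone marrow plates 1 to 3 and -3.63 without plates 4 and 5. There Cdk1 and Cenpa came to -1.93 and -2.28 instead of -1.27 and -1.66. The calls of Ccnb1, Cdk1, Dnmt3a, Dnmt3b, Gmnn and Tyms were lost (adjusted p = 0.0548, 0.148, 0.186, 0.235, 0.236 and 0.189) without fetal liver plate 4. Those of Gmnn and Tyms were made in 23 of 30 and 24 of 30 alternatives.

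After thinning to 20000 UMIs, the share of cells with a UMI of Mki67, a marker of cycling cells, averaged 21.9 ± 6.35% (SD, n = 5 plates) in fetal liver and 8.50 ± 3.29% (SD, n = 5) in bone marrow (exact two-sided permutation p = 0.00794, the smallest possible). The AGM plates had 37.9% and 30.4%. Without thinning the plate means were 57.6%, 34.2% and 14.4% in AGM, fetal liver and bone marrow. Empty wells, which held a median of 24 UMIs in AGM plate 2 and 14 in bone marrow plate 3, had a Mki67 UMI in 0 of 44 and 0 of 24 wells, which allows shares of up to 6.82% and 12.5%. With so few UMIs a well could hardly show Mki67, so these wells speak neither for nor against a background of it. The number of S, G2 and M phase genes detected per cell averaged 38.7 ± 5.86 (SD, n = 5) in fetal liver and 17.8 ± 3.09 (SD, n = 5) in bone marrow (exact two-sided permutation p = 0.00794), and 51.0 in AGM. The highest fetal liver share, 32%, and the lowest bone marrow share, 3.26%, came from the plates with 2 and 18 UMIs per detected gene, so the molecules sampled were not equal between plates. The number of all genes detected after thinning was also lower in bone marrow, at 1914 against 3098. By origin code the Mki67 shares were 20.3% and 24.2% in fetal liver and 6.74% and 11.1% in bone marrow.

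**Figure D4:**
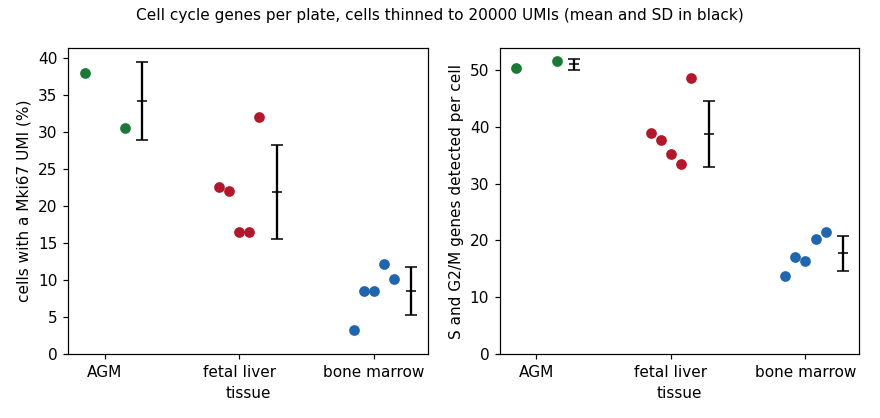
Points are plates, black marks the mean and SD, for the percentage of cells with a Mki67 UMI (left) and the mean number of S, G2 and M phase genes detected per cell (right), after thinning each cell to 20000 UMIs. Every bone marrow plate lies below every fetal liver plate in both panels.

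Of 39 genes described as high in bone marrow stem cells 9 rose and 3 fell between fetal liver and bone marrow (12 rose and 6 fell adjusted over the list alone, camera adjusted p = 0.0318, adjusted p = 0.642 with an estimated correlation), with the adhesion molecule Alcam at 1.05 and 28.7 CPM and Nupr1, a stress-response regulator, at 3.99 and 48.0 CPM. Ly6a rose 2.21-fold, Kit 1.95-fold, and Procr, the protein C receptor, fell 1.91-fold (adjusted p = 0.0458), a call made in 9 of 30 alternatives. Without fetal liver plate 4 the calls of Ly6a, Kit and Procr, bone marrow against fetal liver, were lost (adjusted p = 0.359, 0.183 and 0.371). Slamf1, Cd34, Cd48, Flt3 and Hlf did not pass, with log2 fold changes of -0.04 ± 0.59, -0.35 ± 0.21, -0.55 ± 0.80, -0.83 ± 0.38 and 0.51 ± 0.22. Of 20 megakaryocyte genes 6 rose and 1 fell (9 rose and 1 fell adjusted over the list alone, camera adjusted p = 8.68e-05, adjusted p = 0.310 with an estimated correlation), among them Itga2b (CD41, 9.39-fold) and Pf4, platelet factor 4 (2.93-fold). Apoe rose from 39.7 to 452 CPM. Of the endothelial markers 11 fell (2 rose and 13 fell adjusted over the list alone, camera adjusted p = 0.00489, adjusted p = 0.569 with an estimated correlation), with Ramp2 at 100.4 and 4.38 CPM and Ecscr at 148 and 43.1 CPM. Of 22 glycolysis genes 3 fell (1 rose and 9 fell adjusted over the list alone, camera adjusted p = 0.00131, adjusted p = 0.528 with an estimated correlation). Among them were the glucose transporter Slc2a1 (2.75-fold) and Eno1 (2.21-fold). The calls of Alcam, Itga2b, Pf4, Slc2a1 and Eno1 were lost without fetal liver plate 4 (adjusted p = 0.0626, 0.0806, 0.536, 0.124 and 0.0878). The log2 fold change of Nupr1, 3.58 in all, was 4.25 without bone marrow plates 1 to 3 and 2.34 without plates 4 and 5. There Alcam and Pf4 came to 4.14 and 0.95 instead of 4.75 and 1.55. The calls of Ly6a and Kit were lost (adjusted p = 0.0846 and 0.365) without fetal liver plates 1 to 3. The call of Slc2a1 was lost (adjusted p = 0.161) without plates 4 and 5.

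The count of 732 calls between bone marrow and fetal liver fell to 331 with both tissues fitted alone, 117, 429 and 402 without fetal liver plate 4, fetal liver plate 3 and bone marrow plate 5, 373 or 365 without 1 fetal liver origin and 123 without cells holding at least 5 markers of another cell type. It rose to 1718 or 1958 without 1 bone marrow origin, 1348 when cells with at least 2 UMIs were counted and 2127 with limma (874 and 1253 higher and lower), and with each plate a library 475 and 522 were higher and lower. The limma fit also took plates as libraries, with the origin code as a random block. When cells with at least 1 UMI were counted, which scales to the number of detected genes, 801 and 292 were higher and lower. There 13 genes were called in the opposite direction.

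Between AGM and bone marrow, the leading falls held genes of endothelium and the fetal state and the leading rises held MHC genes. Plvap, Cdh5, Mmrn2, the acyltransferase gene Mogat2, Ddah1, the coagulation factor gene F10 and Nrep had no UMI in bone marrow and were at least 2029-fold, 1063-fold, 952-fold, 756-fold, 694-fold, 675-fold and 518-fold lower. Igf2 fell from 1114 to 0.153 CPM (log2 fold change -12.97 ± 0.50, adjusted p = 6.20e-13). Myl10, a myosin light chain (chromosome 5, 136693146 to 136701094), had no UMI in AGM and was at least 5484-fold higher with 587 CPM in bone marrow, where plates 1 to 3 had 929 CPM and plates 4 and 5 244 CPM (bounds of 2284 and 8683 from 1 origin alone). In bone marrow 819 genes were higher and 561 lower.

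Of the endothelial markers 21 fell in bone marrow against AGM (24 fell adjusted over the list alone, camera adjusted p = 2.09e-26, adjusted p = 0.237 with an estimated correlation), and of the fetal stem cell genes 12 fell (13 fell adjusted over the list alone, camera adjusted p = 1.16e-22, adjusted p = 0.173 with an estimated correlation). A UMI of Cdh5 was found in 0 of 423 bone marrow cells, which allows a share of up to 0.709%. Of 27 imprinted genes 10 fell and 1 rose (2 rose and 10 fell adjusted over the list alone, camera adjusted p = 5.22e-08, adjusted p = 0.173 with an estimated correlation).

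The other leading rises had no UMI in AGM either. H2-Q7 was at least 4401-fold higher, Sdsl 1668-fold (1201 and 2134 from 1 bone marrow origin alone), Cd74, the MHC class II invariant chain, 1507-fold, H2-Q6 1196-fold (862 and 1531), Otos 1037-fold, H2-DMb1, a class II peptide loading chain, 897-fold and Ctss, the lysosomal protease cathepsin S, 675-fold (371 and 978). With 1 plate left out the lowest bounds of Myl10, H2-Q7 and Plvap were 1882-fold, 1509.9-fold and 1359-fold. A UMI of Myl10 was found in 84.6% of bone marrow cells (interval 80.8 to 87.9%) and 30.6% of fetal liver cells, and in 0 of 143 AGM cells, which allows a share of up to 2.10%. Of the MHC class I genes 14 rose (15 rose adjusted over the list alone, camera adjusted p = 3.44e-23, adjusted p = 0.173 with an estimated correlation), and of the interferon response genes 15 rose (19 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.95e-11, adjusted p = 0.173 with an estimated correlation).

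Of the genes of G2 and M phase 26 fell in bone marrow against AGM (35 fell adjusted over the list alone, camera adjusted p = 2.06e-18, adjusted p = 0.447 with an estimated correlation), with Cenpf at 308 and 64.5 CPM and Ccnb1 at 177 and 17.2 CPM. Of the S phase genes 7 fell (7 fell adjusted over the list alone, camera adjusted p = 0.00118, adjusted p = 0.593 with an estimated correlation). Of 77 cytosolic ribosomal protein genes 59 rose (74 rose adjusted over the list alone, camera adjusted p = 2.91e-25, adjusted p = 0.561 with an estimated correlation), among them Rps3a1 (2.51-fold) and Rpl23 (2.504-fold). The estimated correlation between these genes was 0.980, so they moved almost as one and the call of the list may owe to it. Ribosomal protein genes took 14.997% and 15.2% of UMIs on the AGM plates, 20.4% to 27.1% on fetal liver plates and 20.4% to 33.0% on bone marrow plates, of which the plate with the highest share had a median of 29964 UMIs per cell and the plate with the lowest 92658. Of the immediate early genes 9 fell and 1 rose (1 rose and 15 fell adjusted over the list alone, camera adjusted p = 3.54e-07, adjusted p = 0.173 with an estimated correlation), Jun falling 15.1-fold and the growth regulator Myc rising 4.003-fold. The log2 fold changes of Jun and Ccnb1, -3.91 and -3.42 in all, were -3.07 and -2.74 without bone marrow plates 1 to 3 and -5.55 and -4.48 without plates 4 and 5. The calls of Jun, Rps3a1 and Rpl23 were lost (adjusted p = 0.142, 0.165 and 0.188) without fetal liver plate 4, which enters this comparison only through the shared fit. Rps3a1 and Rpl23 also lost them without fetal liver plates 1 to 3 (adjusted p = 0.0557 and 0.0623) and without plates 4 and 5 (adjusted p = 0.0694 and 0.0766).

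Of the bone marrow stem cell list 12 genes rose and 6 fell between AGM and bone marrow (18 rose and 6 fell adjusted over the list alone, camera adjusted p = 0.0256, adjusted p = 0.593 with an estimated correlation). Txnip, an inhibitor of thioredoxin, rose 5.68-fold, Ly6a 8.06-fold and Socs2 20.5-fold, and Cdkn1c fell 14.6-fold. Hlf rose 3.10-fold and Slamf1 from 0.428 to 15.8 CPM. Procr fell 2.62-fold (adjusted p = 0.00559), with a log2 fold change of -1.39 in all and -2.01 without bone marrow plates 4 and 5. Without fetal liver plate 4 the calls of Hlf, Procr and Slamf1, bone marrow against AGM, were lost (adjusted p = 0.0857, 0.144 and 0.0869). Kit, Cd34, Cd48 and Flt3 did not pass, with log2 fold changes of 0.58 ± 0.30, -0.71 ± 0.25, 1.18 ± 1.03 and 1.08 ± 0.48. Apoe did not pass either, at 662 CPM in AGM and 452 CPM in bone marrow. The limma count below took plates as libraries, with the origin code as a random block. The 1380 calls against the single AGM library fell to 329 without fetal liver plate 4 and 864 without bone marrow plate 5. They fell to 771 without cells holding at least 5 markers of another cell type, which left out 138 of 143 AGM and 228 of 423 bone marrow cells. They rose to 2748 or 2466 without 1 bone marrow origin, 2066 when cells with at least 1 UMI were counted (1371 and 695 higher and lower, 12 in the opposite direction), 2432 with at least 2 UMIs and 3610 with limma (1481 and 2129 higher and lower).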

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

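The test of overlapping genes as the whole cause of the loss on fetal liver plate 5 was chosen only after its result was seen.

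On fetal liver plate 5, 10 named genes stood far from the other 4 fetal liver plates. Lymphocyte and progenitor genes were low, with Ltb at 116 CPM against 385 to 431 on the others and Lmo2 at 95.3 CPM against 398 to 514. Several other genes were high, with Car2 at 1274 CPM against 840.4 to 959.8, Prtn3 at 557 CPM against 413 to 453, Cdk1 at 312 CPM against 213 to 236, Tpi1 at 1362 CPM against 942 to 1037, Pf4 at 72.7 CPM against 26.7 to 38.6 and Ctss at 16.5 CPM against 2.96 to 6.002. Near detection were Fos at 0.337 CPM against 0 and Tspan18 at 0.673 CPM against 0 to 0.118.

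On the other fetal liver plates single genes of several kinds differed. Plate 3 had Cd34 at 186 CPM against 255 to 280.2, H2-Aa at 2.52 CPM against 0 to 0.673 and Sdsl at 3.57 CPM against 0. Plate 4 had Igf2bp1 at 32.2 CPM against 58.2 to 65.0, Crip2 at 1.18 CPM against 0 to 0.337, Edn1 at 0.235 CPM against 0 and Nrp1 at 0.118 CPM against 0. Plate 1 had Igf2bp3 at 76.3 CPM against 47.0 to 55.4, Ddah1 at 5.78 CPM against 0 to 0.471 and Mmrn2 at 1.19 CPM against 0, and plate 2 had Plvap at 2.06 CPM against 7.55 to 8.94.

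On bone marrow plates most such values were traces of genes that were otherwise absent there. Plate 1 had Crip2 at 2.72 CPM against 0 to 0.130, Grap at 2.43 CPM against 0, Acta2 at 0.0971 CPM against 0 and Tspan18 at 0.0971 CPM against 0, plate 2 had Cldn5 at 0.135 CPM against 0 and plate 3 had Hbb-y at 0.130 CPM against 0. Plate 4 had Mzb1 at 9.98 CPM against 0 to 0.135, Igf2bp3 at 4.54 CPM against 0 to 0.135 and Fos at 0.454 CPM against 0 to 0.130. Plate 5 had Edn1 at 8.60 CPM against 0 to 0.260, Gja4 at 0.307 CPM against 0 and Nrp1 at 0.307 CPM against 0, and the myeloid gene Plac8 was low there with 224 CPM against 366 to 414. Dixon's test, which singles out by chance about 5% of groups, singled out 34 of 220 combinations of a named gene and a tissue with 5 plates (15.5%), 28 of them on the high side. In 12 of these the other 4 plates were at 0, where any UMI on 1 plate is singled out, so that chance rate does not hold for them.

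Fetal liver plate 5 nearly lacked 59 genes that had a median of at least 100 CPM on the other fetal liver plates and were at least 8-fold lower here, against 0 to 2 on the others. Among them, named after their values were seen, were Dek, a chromatin protein, with 25.7 CPM against a median of 545, and the translation factor genes Eif5 (53.2 against 551) and Eif3f (113 against 929). Fewer UMIs alone did not account for the loss, since thinning plate 4 to the UMIs of plate 5 lost 3.39% of them. At 100 CPM or more random thinning could hardly bring genes down 8-fold. It does not mimic fewer sampled molecules either, which stay open. Overlapping genes are argued against as the whole cause, since 39.0% of the missing genes (interval 26.5 to 52.6%) have an exon that overlaps another gene. A different treatment of overlapping reads on that plate may still have a part, as these genes overlapped others by 1.69 percentage points more than matched genes (interval -11.9 to 15.3), which leaves it open. No biological explanation was tested.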

How the results depend on the processing

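The counts of cells with at least 1 or at least 2 UMIs are the tests here that were chosen after seeing the data.

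The named genes mostly kept direction and call. Of 9037 values of 303 combinations of a gene and a comparison, 7907 kept both, 879 lost the call, 96 gained one, 39 turned direction with a call on either side and 116 turned with no call on either side. Calls among the named genes, 247 in all, numbered 123 to 269 when 1 plate or origin was left out, the fewest without fetal liver plate 4, and 102 without cells holding markers of another cell type. That setting left out 138 of 143 AGM, 335 of 454 fetal liver and 228 of 423 bone marrow cells. Depth was thus lost in every tissue, and few UMIs remained in AGM. Of the list tests 38 passed with the preset correlation in camera and 0 with the estimated one.

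The limma counts here took plates as libraries with the origin code as a random block, so the test and the unit changed together. Calls between fetal liver and AGM, 748 in all, came to 2218 with both tissues fitted alone and 2170 with limma. They came to 557 without cells of other markers, of which 177 were among the 748. With cells with at least 1 and at least 2 UMIs counted they came to 348 and 1809. Between bone marrow and fetal liver the 732 calls came to 331 with both tissues fitted alone, 2127 with limma, 123 without cells of other markers, and 1093 and 1348 with cells with at least 1 and at least 2 UMIs counted, of which 13 and 10 were called in the opposite direction. For bone marrow against AGM the 1380 calls came to 3610 with limma, 771 without cells of other markers, and 2066 and 2432 with cells with at least 1 and at least 2 UMIs counted, 12 and 8 in the opposite direction. Leaving out 1 plate or origin gave 181 to 2186, 117 to 1958 and 329 to 2748 calls in the 3 comparisons, the fewest without fetal liver plate 4 and the most without a bone marrow origin. A tissue left with 1 library was assumed to vary like the others. Without fetal liver plate 4 its origin code was left with plate 5 alone, which nearly lacked 59 genes. The spread is shared by all comparisons, so calls lost in that setting need not rest on plate 4. The cause of these shifts was not tested.

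With each plate a library and the plate number as a replicate block the calls numbered 594, 846 and 982, and without the block 608, 997 and 1216. Residual profiles of plates with one number correlated across genes, which are not independent replicates, at 0.0140 to 0.0916, and the best partner had the same number for 2 of 3 numbers, so the numbers were not taken to pair plates.

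Without cells holding markers of another cell type, fetal liver against AGM turned for Gas2l3 (0.50), Itgb3 (2.53), Plek (7.30) and Ppp1r15a (8.80), and bone marrow against AGM for Btg2 (9.26), all log2 fold changes. When cells with at least 1 UMI were counted, fetal liver against AGM turned for H19 (0.17) and Wdr43 (0.13), bone marrow against fetal liver for Cks1b (0.22), Eno1 (0.30), Nme1 (0.49) and Sdhb (0.33), and bone marrow against AGM for Apoe (0.93), Cd34 (0.70), Procr (0.15), Rbbp4 (0.71) and Tyms (0.0487). With at least 2 UMIs it turned for Malat1 (0.65), Rbbp4 (0.48) and Wdr43, fetal liver against AGM (0.0674), for Eno1 (0.20), Nme1 (0.39), mt-Cytb (0.38) and Sdhb, bone marrow against fetal liver (0.0204), and for Apoe (0.99), Cd34 (0.58) and Rbbp4 (0.63) in bone marrow against AGM. In 21 of these 21 turns in counts of cells the share of cells with the gene kept the direction of the UMI result. Many shares were close to 100% in 1 tissue. The turns thus came with the scaling of cell counts to detected genes. But the shares were neither thinned nor scaled, and the lower one always lay in the tissue with fewer genes detected per cell. Most genes would lean that way, so the shares speak neither for nor against the UMI results. The cause of the turns without cells of other markers was not tested.

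With 1 plate or origin left out, direction turned with a call on either side for Xist (-7.59 to 1.48), Ddx3y (-8.67 to 3.57) and Eif2s3y (-10.50 to 2.47) in fetal liver against AGM, and Xist (-11.60 to 7.85), S100a9 (-2.55 to 10.80), Ddx3y (-10.43 to 11.45), Eif2s3y (-8.29 to 12.36) and Uty (-6.03 to 7.30) in bone marrow against fetal liver, and Cd48 (-2.82 to 10.85), Xist (-11.12 to 1.24), Ddx3y (-8.78 to 4.68), Eif2s3y (-6.83 to 2.88) and Uty (-5.64 to 6.60) in bone marrow against AGM, the ranges being log2 fold changes. Xist and the Y chromosome genes differed between the origin codes of a tissue, so leaving out a code changes them by construction. S100a9 and Cd48 differed too, at 23.6 and 28.4 CPM in bone marrow plates 1 to 3 and 0 and 0.931 CPM in plates 4 and 5. Cd48 also stood at 0 and 19.3 CPM on AGM plates 1 and 2. Why S100a9 and Cd48 differed was not tested.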

Other observations

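The bounds of each test in this part were set before its result was seen, but on patterns already noticed in these data, except for the split of plates, which was planned.

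Genes of blood lineages moved in both directions between AGM and fetal liver. Car2, the carbonic anhydrase of erythroid cells, rose 4.61-fold, Ltb, the lymphotoxin beta gene, 7.43-fold, Cd27 4.10-fold, Lmo2, a transcriptional partner of blood progenitors, 3.55-fold and Prtn3, a neutrophil protease, 2.63-fold. Vwf, the von Willebrand factor of endothelium and platelets, fell 5.86-fold and the keratin Krt18 2.36-fold. Cpa3, a mast cell protease, was at least 413-fold lower with 45.0 CPM in AGM and no UMI in fetal liver, but AGM plates 1 and 2 had 23.9 and 85.8 CPM, 1 AGM cell held 29.6% of its AGM UMIs and the lowest bound with 1 plate left out was 217-fold. Hba-a1 and Afp had no UMI in AGM and were at least 125-fold and 112-fold higher, at 13.4 and 12 CPM in fetal liver (43.0-fold and 38.5-fold at the lowest with 1 plate left out). Of 22 lymphoid genes 4 rose and 1 fell (7 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0852, adjusted p = 0.555 with an estimated correlation), and of 11 mast cell genes 1 fell (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0528, adjusted p = 0.555 with an estimated correlation). The calls of Ltb, Cd27, Lmo2, Prtn3, Vwf and Krt18 were lost (adjusted p = 0.146, 0.0661, 0.638, 0.0848, 0.0540 and 0.138) without fetal liver plate 4. Krt18 also lost it without plates 1 to 3 (adjusted p = 0.0550).

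In bone marrow against fetal liver, several myeloid genes rose, Prtn3 1.83-fold and Plac8 1.97-fold among them. Nkg7 of the lymphoid list, a granule protein of cytotoxic cells, rose 10.3-fold, while Mgst3, a glutathione transferase, fell 2.23-fold. Of 22 lymphoid genes 2 rose and 1 fell (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.413, adjusted p = 0.809 with an estimated correlation). Of 24 neutrophil and monocyte genes 4 rose (4 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.545, adjusted p = 0.809 with an estimated correlation). Krt18 rose 3.56-fold and the nuclear RNA Malat1 2.02-fold. Against AGM, Fdps of cholesterol synthesis fell 2.30-fold. Of 24 cholesterol genes 1 rose and 1 fell (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.0431, adjusted p = 0.447 with an estimated correlation). The calls of Prtn3, Plac8, Mgst3 and Malat1 were lost (adjusted p = 0.425, 0.325, 0.159 and 0.287) without fetal liver plate 4. They were also lost without fetal liver plates 1 to 3 (adjusted p = 0.237, 0.0725, 0.0754 and 0.242) and, except for Mgst3, without plates 4 and 5 (adjusted p = 0.249, 0.162 and 0.551). Fdps, bone marrow against AGM, lost its call without fetal liver plate 4 (adjusted p = 0.194).

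Plvap, Cldn5 and Cdh5 were among the endothelial genes higher in AGM than in fetal liver. Wells with more detected genes are argued against, since in 133 pairs of wells matched on genes detected after thinning the AGM wells still had 6 endothelial markers more (9 against 3, bootstrap interval 6 to 8). Whether separate endothelial cells lay among the AGM wells could not be decided. The 36 AGM wells with the most endothelial markers, at least 17 of 26, were compared with the other 107. Both had a median of 4 of 6 blood genes (difference 0, bootstrap interval -1 to 0.5). But 99.3% of AGM wells held at least 3 of these markers, with a median of 15. Hardly any wells low in markers were thus left as a reference, so that difference speaks neither for nor against such cells. Ptprc alone was lower in the wells with the most markers, at 27.8% against 40.2% of the others. Runx1, Gfi1 and Gfi1b are also expressed in blood-forming endothelium, so separate endothelial cells stay open. An endothelial programme within AGM blood stem cells may be a hypothesis for this pattern, and the tissue, its single origin code and RNA from other cells in each well stay open, as untested.

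Xist and Y chromosome genes were both present in the AGM library. Of 36 AGM wells with at least 3 UMIs of Xist or of Y chromosome genes 0% had both (which allows a share of up to 8.33%), as cells of both sexes pooled under one origin code would give. That test is weak by itself, because independent detection in single wells would give 2.26 such wells and none with a probability of 0.0756. Cells of both sexes pooled from several embryos may therefore lie behind this code, and whether other codes are single animals is not known.

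The difference between bone marrow and fetal liver was set against other splits of the 10 plates, each plate a library. The real split called 830 of 11045 genes in edgeR, H19, Igf2 and H2-Q7 being genes of that contrast, and the highest of the other splits called 0 (2276 against 997 at an unadjusted p under 0.05). 1 of 100 splits, the real one, gave as many, which excludes a random split of plates as its source only if plates are independent, and plates of one origin code may not be. Mixed splits carry the tissue difference within their groups, and the origin codes allow too few splits for such a test.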
